A study of Rattus norvegicus with 2 samples.

How the data were processed

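Two-colour arrays compared RNA of uncultured rat lung cells (Cy3) with RNA of mix1 (Cy5), a mixture of rat bone marrow cells and rat primary ear fibroblasts that were both grown in medium with fetal bovine serum, per the labels. Per the labels' protocols, total RNA was isolated from cell pellets with TRIzol and cleaned on silica columns. The submitters' processing notes name Agilent Feature Extraction. Its version, the background correction, the dye normalization and the centring are not given in the sources used here. Scanner intensities were not used here.

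The deposited table holds 1 value per probe and array, which were taken as log2 ratios of the channels. No source states the log base. The values run from -11.74 to 9.09, which as base-10 logarithms would exceed the range of a 16-bit scanner, and fold changes printed here rest on base 2. The authors' deposited log2 values were used as they stand: the probe medians are -0.16 in replicate 1 and -0.21 in replicate 2, so the arrays were not centred on the median probe, and what they were centred on stays unknown. No value is missing or exactly 0, and none repeats at the ends of the range, so the planned filter on such values removed nothing and was not run. The direction, lung over mix1, is likely: it was taken from the wording of the series and the sign of 6 lung genes fixed beforehand.

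Probes were named from GEO's platform annotation, which lists 20417 of the 40012 probes, each with 1 symbol and none with several. The other 19595 probes are unnamed here. Symbols were updated through RefSeq accessions without versions (16987 probes), or else by current symbol (3035) or synonym (387), against the gene table of assembly GRCr8, and 8 probes kept the annotation's symbol. No coordinates are given, because the arrays name no genome build. Probes of 1 gene were averaged, which applied to 3767 of 15611 genes. In 34 genes, probes were at least 2-fold from 0 in opposite directions in both arrays.

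Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The fit had 1 residual degree of freedom and 1.28 prior degrees of freedom. Lists of genes for cell types, pathways and states were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 38 lists with at least 5 measured genes were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. The named genes are the 15 highest and 15 lowest past the threshold with the same sign in both arrays, up to 4 genes per list in its direction, up to 2 against it, and the 6 direction genes. Values are given as the mean ± SD of 2 arrays on the log2 scale.

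The tests were run on simulated data for the comparison of lung with mix1, with 15611 genes and the estimated spread. With 200 genes changed, 0% of the 50 genes changed by a log2 size of 1 were called, against 66% of those changed by 2 and 84% of those changed by 4, and 3.85% of calls were unchanged genes. In the real data many more genes passed (12907), 7578 of them under 2-fold in the mean, so these rates do not carry over. With 1 of every 2 genes changed by amounts drawn from the real ratios, 2.12% of 5990 calls were unchanged genes. At an unadjusted p under 0.05, camera called 4 of 100 random lists of 20 genes, and all 100 when shifted by a log2 size of 2. The simulated genes were independent of each other, so this does not check the preset correlation for real lists. The simulations hold no dye effect.

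The alternatives were array medians subtracted, scaling between arrays, robust eBayes, treat, single probes, the median probe of a gene (the lower of the middle probes where their number is even, which lowers such genes), an adjusted p under 0.01, estimated correlation, ranks, leaving out each array, and leaving out genes whose probes disagree, the last chosen after seeing the data.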

Results

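Gene expression was measured in uncultured rat lung cells by hybridising lung RNA against a common control RNA on 2 two-colour Agilent oligonucleotide arrays. The control, called mix1, was a mixture of cultured rat bone marrow cells and cultured rat primary ear fibroblasts. The group lung held 2 samples, replicates 1 and 2, and each array carried lung RNA in Cy3 and mix1 RNA in Cy5. The comparison asked how gene expression in lung differs from that of these cultured adult cells. The table held 40012 probes, of which 20417 carried a gene name, and these gave 15611 genes. The precision of every value was limited by the number of arrays. Because no label says that the lung samples came from separate animals, p-values measured only the spread between these samples, which may be technical. Mix1 entered as 1 control RNA, so its own spread was left out, and no array had the dyes swapped, so a dye effect could not be separated from the difference between the RNAs.

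The sign of the deposited values was read as lung over mix1, which is likely and not stated outright: the series describes the values as the difference of lung from mix1, whereas the scanner software's own log ratio is Cy5 over Cy3, here mix1 over lung. With lung over mix1, the surfactant protein genes of the alveolar epithelium had log2 ratios of 7.02 ± 0.02 (SD, n = 2) for Sftpc, 6.11 ± 0.09 for Sftpa1, 5.70 ± 0.04 for Sftpb and 5.58 ± 0.02 for Sftpd. The club cell secretory protein gene Scgb1a1 lay at 4.91 ± 0.01 and Ager, a receptor abundant on alveolar type 1 cells, at 3.94 ± 0.12. The median of these 6 genes was 5.66 in replicate 1 and 5.62 in replicate 2. They were used to settle the sign and are therefore no evidence of a difference. With the sign turned, every direction given here would be the opposite.

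The replicates gave nearly the same ratios. Across genes, which are not independent replicates, Pearson's r between the arrays was 0.983 and Spearman's rho was 0.968. The median SD of a gene between the arrays was 0.051 on the log2 scale. In both arrays, 2572 genes were at least 2-fold higher and 2466 at least 2-fold lower in lung, together 32.3% of the genes tested. With array medians subtracted, 2958 were higher and 1887 lower. The difference between the arrays divided by 2 holds array noise and any difference between the lung samples, but not that between lung and mix1. It reached the same 2-fold size for 20 genes, and no gene was 2-fold apart in opposite directions. At least 16-fold differences in both arrays were found for 334 genes higher and 153 lower in lung. In limma's moderated test against 0, 5142 genes were higher and 7765 lower in lung at a Benjamini-Hochberg adjusted p under 0.05. Together they make up 82.7% of the genes tested. Counts of higher or lower genes in a list or family stand against these 5142 higher and 7765 lower among all 15611 genes. Of these calls, 7578 were under 2-fold in the mean, and 4024 genes passed when limma's treat was run against a 2-fold change. The split of calls depended on centring: as deposited, 60.2% of calls were lower in lung, and with each array's median subtracted, which raised the median gene by 0.19, 49.7% were. If the sign of the ratios were turned, the 60.2% would be higher in lung.

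**Figure D1:**
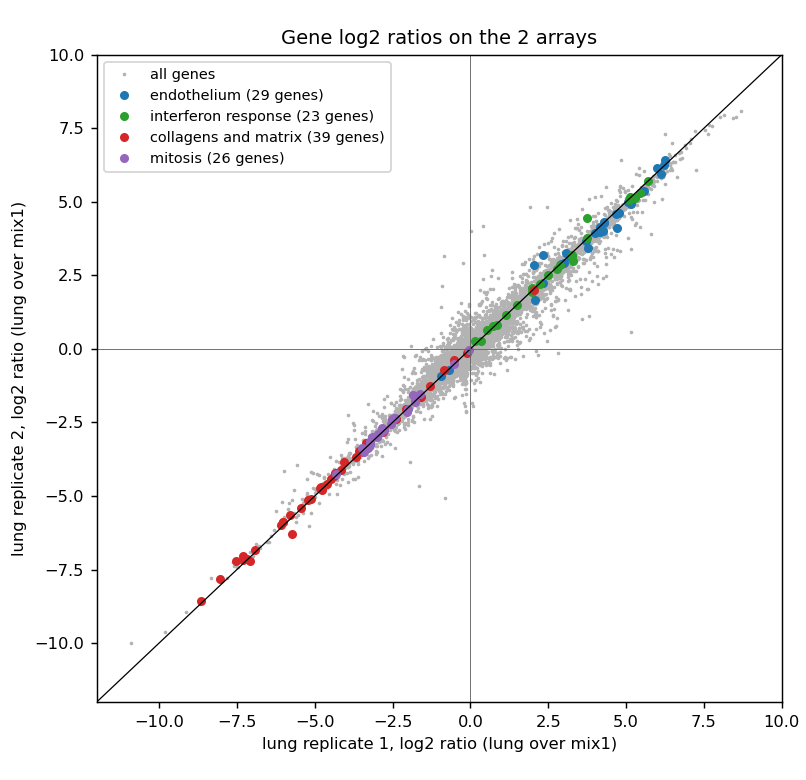
Log2 ratio of each gene, lung over mix1, in lung replicate 1 (horizontal axis) against lung replicate 2 (vertical axis); grey points are all 15611 genes, coloured points are the members of 4 gene lists, and the diagonal marks equal ratios. Endothelial and interferon genes lie mostly at the upper right and matrix and mitosis genes mostly at the lower left, close to the diagonal.

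The highest ratio belonged to Clec1b, the platelet receptor CLEC-2, at 8.38 ± 0.44 (SD, n = 2), or 334-fold. It was followed by Ccdc68 at 8.19 ± 0.47, the retinaldehyde dehydrogenase Aldh1a1 at 8.15 ± 0.41, multimerin 1 (Mmrn1) at 8.05 ± 0.14 and the epithelial adhesion molecule Epcam at 7.95 ± 0.09. The other genes among the 15 highest were Rnase3, the calprotectin subunit S100a9, the lung flavin mono-oxygenase Fmo2, Stfa2l3, the prostaglandin-degrading enzyme Hpgd, Lamp3, Sftpc, Ifitm6, Cyp2f4 and C8h11orf97, with ratios from 7.66 down to 6.78. At the other end, the stromelysin gene Mmp3 had a log2 ratio of -10.44 ± 0.64, or 1389-fold lower in lung. The BMP antagonist Grem1 lay at -9.72 ± 0.13, Ccn4 at -9.03 ± 0.13, osteopontin (Spp1) at -8.69 ± 0.01 and Col11a1 at -8.62 ± 0.06. The fast skeletal myosin gene Myh1 lay at -8.06 ± 0.38, and Adh7, Thbs2, Tnn, Has2, Ccl7, Lrrn4cl, Prrx1, Tnc and Col1a1 completed the 15 lowest, between -7.99 and -7.25. Passing limma's test was a condition for choosing these 30 genes, and their adjusted p ran from 0.00117 to 0.00344. How background was handled is not given in the sources used here, and it sets the size of ratios in which one channel is dim. The SDs cover the arrays and not the probes of a gene. Most of the 213 named genes were measured by a single probe and could not move when the lower middle probe stood for the gene. With that probe, 23 of the 213 moved by more than 1.5-fold, so the share among genes with several probes is larger. Grem1 then lay at -11.62, below Mmp3, Twist1 at -7.12, Slc34a2 at 2.94, Lyve1 at 3.92, Gpm6a at 3.74, Bank1 at 3.74, Rsad2 at 4.02 and Gucy1a1 at 2.77. Smaller moves of that kind were seen for Thbs2, Col1a1, Clic5, Clec14a, Cma1, Tp63, Ccne1, Elovl6, Chac1 and Sftpb.

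**Figure D2:**
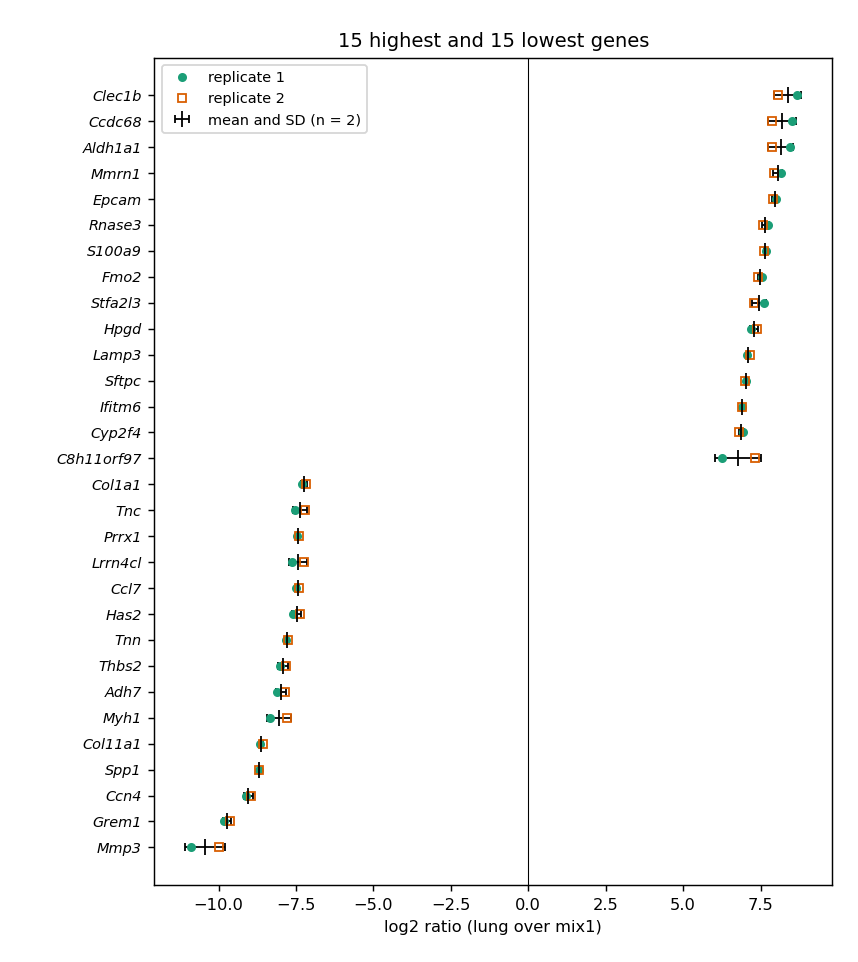
Log2 ratio, lung over mix1, of the 15 highest and 15 lowest genes past the threshold; circles are replicate 1, squares replicate 2, and vertical ticks with horizontal bars the mean and SD (n = 2). The values run from -10.44 for Mmp3 to 8.38 for Clec1b. The replicates of each gene lie on the same side of 0, which the rule for choosing these genes required.

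Genes of the lung epithelium were higher in lung. The genes used to settle the sign mark alveolar and secretory cells, so the direction of lists for these cells was largely set with it. All 14 measured genes of the alveolar type 2 list were higher, with a median log2 ratio of 4.41. Examples are Lamp3 at 7.11 ± 0.05 (SD, n = 2), the chitinase gene Chia at 6.59 ± 0.18, the phosphate transporter Slc34a2 at 5.74 ± 0.16 and Muc1 at 5.33 ± 0.07. In the alveolar type 1 list, 11 of 12 genes were higher (median 4.52), led by Akap5 at 6.33 ± 0.12, Spock2 at 5.92 ± 0.06 and Clic5 at 5.92 ± 0.47, while Igfbp2 was lower at -1.67 ± 0.04. All 11 airway secretory genes were higher (median 4.42), among them Cyp2f4 at 6.87 ± 0.08, Cyp2a3 at 5.98 ± 0.22 and keratin 19 (Krt19) at 5.58 ± 0.11. Of 20 motile cilia genes, 18 were higher and 2 did not pass (median 3.30). The dynein light chain Dynlrb2 lay at 5.79 ± 0.06 and Foxj1, the transcription factor of motile ciliogenesis, at 4.73 ± 0.14. Each of these counts was the same when adjusted over the list alone. With 82.7% of all genes passing, both adjustments are mild and use the same p-values, so such agreement, here and below, is little support. In limma's camera, which compares a list with the other genes, adjusted p was 8.94e-07 for type 2, 3.24e-05 for type 1, 8.03e-06 for secretory and 1.39e-07 for cilia genes. With an estimated correlation, a fit that has 1 residual degree of freedom here, adjusted p = 0.475 for each of these lists. No list of the 38 reached an unadjusted p under 0.05 in that fit, so its result, here and below, neither removes nor adds support.

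Endothelial genes were also higher in lung, and mesenchymal and muscle genes were mixed. Of 29 endothelial genes, 26 were higher and 3 lower, with a median of 4.07. Cyyr1 lay at 6.33 ± 0.12 (SD, n = 2), Clec14a at 6.23 ± 0.01, the hyaluronan receptor Lyve1 at 6.06 ± 0.10 and the VEGF receptor Kdr at 6.04 ± 0.11, whereas the endothelin receptor Ednrb lay at -1.72 ± 0.02 and the sphingosine phosphate receptor S1pr1 at -0.92 ± 0.02. Of 12 transcription factors and signals of lung mesenchyme, 9 were higher and 2 lower (median 1.74). Wnt2b (3.99 ± 0.15), Tcf21 (3.50 ± 0.07) and Gata6 (3.30 ± 0.08) were higher, and Osr1 (-3.37 ± 0.02) and Fgf10 (-2.33 ± 0.16) were lower. Of 10 mesothelial genes, 8 were higher and 1 lower (median 1.14), led by Gpm6a at 5.73 ± 0.01 and Krt18 at 5.22 ± 0.02, a keratin that airway and alveolar epithelium also express. Of 16 cardiac muscle genes, 7 were higher, 2 lower and 7 did not pass (12 higher and 1 lower with array medians subtracted). Troponin I (Tnni3) lay at 4.43 ± 0.25, the cardiac myosin heavy chain Myh6 at 3.45 ± 0.13 and the atrial light chain Myl7 at 3.44 ± 0.01. The 2 lower genes were Hspb7 (-0.70 ± 0.08) and Nppa (-0.38 ± 0.03). The camera adjusted p was 4.02e-08 for endothelium, 0.0106 for lung mesenchyme, 0.00132 for mesothelium and 0.00888 for cardiac muscle. With an estimated correlation, adjusted p = 0.475 for endothelium and mesothelium, 0.479 for lung mesenchyme and 0.641 for cardiac muscle. Smooth muscle genes split, with 3 of 12 higher and 7 lower (median -1.03; camera adjusted p 0.441, and 0.0306 without replicate 1). Tagln at -3.89 ± 0.02 and Cnn1 at -3.29 ± 0.09 were lower and desmin (Des) at 2.04 ± 0.13 was higher. The counts of these 5 lists were the same when adjusted over the list alone.

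Genes of immune and blood cells were higher in lung, unevenly between cell types. Of 24 T and natural killer cell genes, 21 were higher and 1 lower (median 3.49). The T cell receptor component Cd3g lay at 6.18 ± 0.21 (SD, n = 2) and the chemokine Ccl5 at 5.34 ± 0.11. The exception was Thy1 at -3.92 ± 0.28, which fibroblasts and marrow stromal cells also express. Of 9 genes of MHC class II presentation, 8 were higher, with RT1-Da at 5.31 ± 0.03 and the invariant chain Cd74 at 4.42 ± 0.02. RT1-DMa was lower at -0.18, a call that ended at 0.01 (adjusted p 0.873) when array medians were subtracted. Of 11 B cell genes, 9 were higher (median 2.09), including Bank1 at 5.06 ± 0.17 and Cd79b at 3.37 ± 0.13. Of 11 mast cell genes, 10 were higher (median 2.37), including Hpgds at 3.75 ± 0.09 and the chymase Cma1 at 3.38 ± 0.03. Of 19 neutrophil genes, 15 were higher and 1 lower (median 2.03), with S100a8 at 6.18 ± 0.03 and Mmp8 at 5.24 ± 0.05 among the higher, and Il1b lower at -1.11 ± 0.02. Macrophage genes were the most divided: 16 of 24 were higher and 6 lower (median 0.96). The mannose receptor Mrc1 lay at 2.59 ± 0.01 and Fcgr3a at 4.76 ± 0.01, while the scavenger receptor Msr1 lay at -2.49 ± 0.07 and Cd14 at -2.51 ± 0.01. Red cell genes moved with these lists: 10 of 12 erythroid genes were higher and 2 lower (median 2.48), with beta globin (Hbb) at 3.94 ± 0.07 and the haem synthesis enzyme Alas2 at 3.55 ± 0.0032. Each of these counts was the same when adjusted over the list alone. The camera adjusted p was 2.64e-07 for T and natural killer cells, 0.000572 for MHC class II, 0.000254 for B cells, 9.22e-05 for mast cells, 7.08e-05 for neutrophils, 0.00302 for macrophages and 0.00201 for erythroid genes. With an estimated correlation, adjusted p = 0.479 for MHC class II and 0.475 for the other 6 of these lists.

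All 23 measured genes of the interferon response were higher in lung, with a median of 2.74. The antiviral GTPases Mx1 and Mx2 lay at 5.71 ± 0.01 (SD, n = 2) and 5.13 ± 0.02, Rsad2 at 5.38 ± 0.11 and the chemokine Cxcl9 at 5.20 ± 0.13. Complement and coagulation genes were divided, 14 of 23 higher and 8 lower (median 1.02). F5 is counted as lower at -0.41, although its 2 probes lay at -3.10 and 2.28. Complement factor B (Cfb, 5.07 ± 0.01), Cd59b (3.48 ± 0.01) and thrombomodulin (Thbd, 3.12 ± 0.01) were higher, and the complement regulator Cd55 (-4.66 ± 0.12) and the protease inhibitor Tfpi2 (-3.79 ± 0.01) were lower. Enzymes of xenobiotic metabolism were higher for 23 of 28 genes and lower for 4 (median 1.48). Fmo2 lay at 7.49 ± 0.07, Cyp2f4 at 6.87 ± 0.08, the carboxylesterase Ces1d at 6.15 ± 0.03 and Cyp1a1 at 5.71 ± 0.19, in contrast to Cyp1b1 at -5.44 ± 0.42. The same counts were obtained when adjusted over the list alone. The camera adjusted p was 1.10e-08 for interferon, 1.26e-06 for xenobiotic metabolism and 0.0378 for complement and coagulation, and with an estimated correlation adjusted p = 0.475 for each. The estimated correlations were 0.004 for interferon and -0.04 for complement genes, under the preset 0.01. Their calls were therefore not lost to a larger estimate, in a setting with 1 residual degree of freedom. With 2 arrays such an estimate rests only on which array was higher for each gene, so it does not show how correlated the genes are. The complement call was also lost with camera on ranks (adjusted p 0.101), with array medians subtracted (0.0644) and in either array alone (0.116 without replicate 1 and 0.123 without replicate 2).

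Genes of extracellular matrix and of attached, spread cells were lower in lung. Of 39 collagen and matrix genes, 37 were lower and 1 higher (38 and 1 adjusted over the list alone), with a median of -4.61. Col11a1, thrombospondin 2 (Thbs2, -7.92 ± 0.15; SD, n = 2), tenascin C (Tnc, -7.37 ± 0.21) and Col1a1 (-7.25 ± 0.09) were the lowest, and Timp3 was higher at 2.03 ± 0.03. All 18 matrix protease genes were lower (median -3.02), led by Mmp3 and followed by Mmp12 at -6.38 ± 0.02 and Mmp2 at -6.22 ± 0.12. All 29 genes of the cytoskeleton and adhesion of cultured cells were lower (median -2.11), including galectin 1 (Lgals1, -4.89 ± 0.16), the collagen-binding integrin Itga11 (-4.66 ± 0.08) and tropomyosin 2 (Tpm2, -4.41 ± 0.05). Of 21 transcription factors of limb and skin mesenchyme, 19 were lower and none passed as higher (median -1.75; 17 lower and 1 higher with array medians subtracted). Hoxa3, chosen after its values were seen, was at least 2-fold higher in both arrays, at 2.22 ± 1.29, and did not pass limma's test (adjusted p 0.0642). Prrx1 lay at -7.44 ± 0.03, Twist1 at -5.66 ± 0.30 and Prrx2 at -5.31 ± 0.09. Counts of the last 3 lists were the same when adjusted over the list alone. The camera adjusted p was 2.13e-08 for collagens and matrix, 1.91e-05 for proteases, 1.08e-06 for cytoskeleton and 0.000771 for the transcription factors, and with an estimated correlation adjusted p = 0.475 for each.

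Proliferation genes were lower in lung. Of 26 mitosis genes, 25 were lower and 1 did not pass (median -2.66). The mitotic kinesin Kif20a lay at -4.28 ± 0.06 (SD, n = 2), the checkpoint kinase Ttk at -3.46 ± 0.05 and Cdk1 at -3.42 ± 0.07. All 28 DNA replication genes were lower (median -2.01), among them cyclin E1 (Ccne1, -2.98 ± 0.03) and Cdc6 (-2.79 ± 0.05). In the list for growth arrest and senescence, 15 of 17 genes were lower (median -1.63; 12 lower and 2 higher with array medians subtracted). Besides the cell cycle inhibitor Cdkn2a at -4.10 ± 0.03, its lowest members were secreted cytokines that are not arrest genes themselves: Ccl2 at -6.92 ± 0.04, Il6 at -4.87 ± 0.08 and Cxcl1 at -3.78 ± 0.03. Immediate early genes were lower for 16 of 19 and higher for 3 (median -0.83; 12 lower and 3 higher with array medians subtracted). Fosl1 lay at -5.88 ± 0.52, Egr1 at -3.58 ± 0.0025 and Fos at -3.47 ± 0.02. Heat shock and unfolded protein response genes were lower for 19 of 22 (median -0.90), with Chac1 at -3.85 ± 0.20 and Hspa1a at -2.46 ± 0.08. The counts were the same when adjusted over the list alone. The camera adjusted p was 1.26e-06 for mitosis, 1.64e-06 for replication, 0.00170 for arrest and senescence, 0.0114 for immediate early genes and 0.000512 for heat shock, and with an estimated correlation adjusted p = 0.475 for each.

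Among metabolic lists, sterol synthesis and glycolysis were lower in lung and respiration was not called. All 17 cholesterol synthesis genes were lower (median -2.96), including lanosterol synthase (Lss, -4.37 ± 0.06; SD, n = 2) and Cyp51 (-3.46 ± 0.07). Of 17 glycolysis genes, 15 were lower and 1 higher (median -1.30), with Pgk1 at -2.28 ± 0.01 and Gapdh at -1.86 ± 0.01 lower and Pfkp at 0.60 ± 0.01 higher. The camera adjusted p was 1.91e-05 for cholesterol synthesis and 0.00267 for glycolysis, and with an estimated correlation adjusted p = 0.475 for both. Oxidative phosphorylation genes had 14 higher and 10 lower of 29, and 18 and 9 with array medians subtracted (median 0.14; camera adjusted p 0.128). Ribosomal protein genes had 8 higher and 19 lower of 36, and 11 and 13 with array medians subtracted (median -0.25, against -0.22 for all genes; camera adjusted p 0.478). Fatty acid and surfactant lipid genes had 7 higher and 10 lower of 21, with a camera adjusted p of 0.952. With array medians subtracted, 9 were higher and 7 lower, and their median went from -0.11 to 0.07. The phospholipase Pla2g1b lay at 4.54 ± 0.23 and the elongase Elovl6 at -4.34 ± 0.02.

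The remaining lists were not called by camera. Circadian clock genes had 7 higher and 7 lower of 15 (median 0.13, adjusted p 0.488): Per2 (2.35 ± 0.01; SD, n = 2) and Dbp (1.97 ± 0.04) were higher, while Bmal1 (-2.15 ± 0.10) and Nfil3 (-2.17 ± 0.02) were lower. Genes of bone, cartilage and fat had 7 higher and 11 lower of 20 (adjusted p 0.923), and their median of -0.44 and mean of -0.30 had the opposite sign to the test. Alkaline phosphatase (Alpl, 4.72 ± 0.01), Cd36 (3.96 ± 0.04) and Adipoq (3.61 ± 0.14) were higher, and osteopontin (Spp1) and Comp (-5.94 ± 0.14) were lower. Blood vessel tone genes had 8 higher and 8 lower of 17 (adjusted p 0.486), with a median of -0.22 against a mean of 0.79 and a positive test. The angiotensin-converting enzyme Ace lay at 4.29 ± 0.01 and both subunits of soluble guanylate cyclase were higher (Gucy1a1, and Gucy1b1 at 3.75 ± 0.09), whereas adrenomedullin (Adm) lay at -3.62 ± 0.02. Epidermal genes had 1 higher and 6 lower of 12 (median -0.32, adjusted p 0.449), with Krt15 at 4.50 ± 0.04 and Tp63 at -2.63 ± 0.22. Pluripotency genes had 2 higher and 3 lower of 9 (adjusted p 0.873), with a median of -0.37, a mean of 0.19 and a negative test. Sox2, which airway epithelium also expresses, lay at 2.57 ± 0.0012. Adjusted over the list alone, the counts of the metabolic lists and of these lists were the same.

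**Figure D3:**
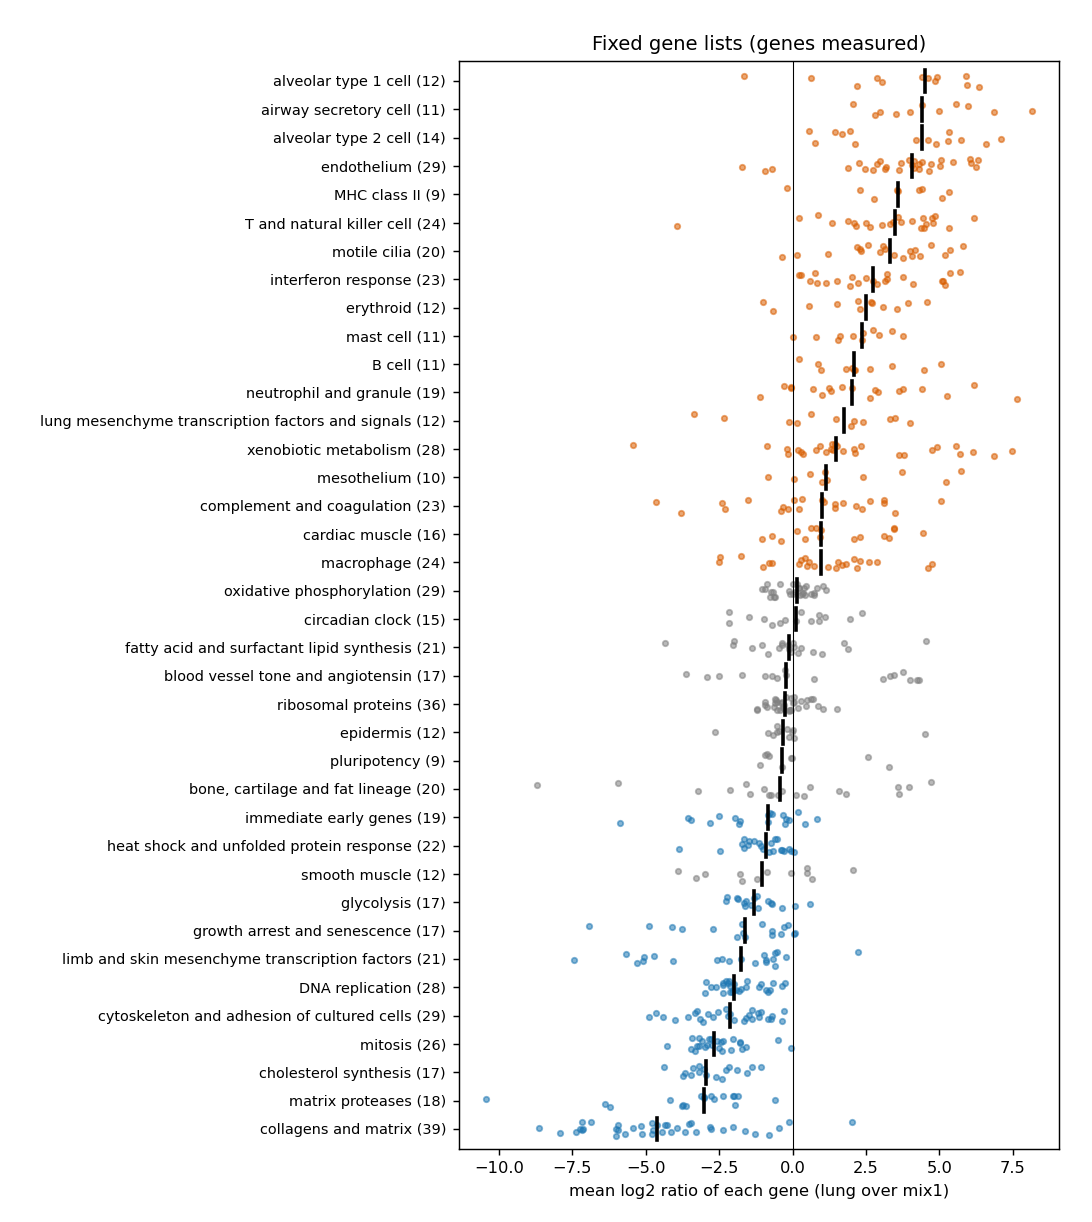
Mean log2 ratio, lung over mix1, of each measured gene (points, horizontal axis) in the 38 fixed gene lists (rows, with the number of genes measured); black bars are list medians, and orange, blue and grey mark lists called higher, called lower or not called by camera with a preset correlation. The medians run from -4.61 for collagens and matrix to 4.52 for alveolar type 1 cells.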

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

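The test that asks for more than a 2-fold change (treat) left 4024 genes, 2143 higher and 1881 lower in lung. With an estimated correlation, camera called 0 of the 38 lists (0 higher, 0 lower). At an unadjusted p under 0.05 it called 0, the smallest p being 0.0946. The preset correlation called 29, and limma's fry, which does not compare a list with other genes, 35. With 2 arrays the estimated setting has 1 residual degree of freedom, and its correlation rests only on which array was higher for each gene. The lists of 11 genes for airway secretory, B and mast cells all had an estimate of 0.3455. The setting also lost the interferon list, whose estimated correlation of 0.004 is under the preset 0.01. Lost calls there therefore do not measure correlation between genes, and the preset value stays unchecked. The other alternatives kept the count of genes past the threshold between 9575 and 13373, the count 2-fold apart in both arrays between 4845 and 5097 (5367 and 5568 in either array alone) and the count of called lists at 28 or 29. Subtracting array medians changed the split to 6007 higher and 5931 lower. Of 12907 calls, 11050 were shared with that setting, each in the same direction. Among 213 named genes, RT1-DMa went from -0.18 to 0.0104 with array medians subtracted, and Ldb3 went from 0.50 to -0.23 with the lower middle one of its 4 probes, both reversals in sign. The cause was not tested, beyond RT1-DMa lying within the shift of the medians. Nppa (-0.19, adjusted p 0.0513, array medians subtracted) and Tfcp2l1 (0.68, adjusted p 0.0866, lower probe) kept their direction and no longer passed limma's test. Smooth muscle was called lower without replicate 1 (adjusted p 0.0306, against 0.0585 to 0.768 under the other alternatives), where lists were tested on the log ratios of a single array, which is another statistic. Leaving out an array leaves no residual degrees of freedom, so genes then have values but no test. Lung and mix1 were paired on each array, and testing their log ratios against 0 used this pairing. No other pairing was possible because the labels give a single group of lung samples. Signal over background is not known here, so dim probes could not be set apart.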

Other observations

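The gene families here were chosen after their values were seen, from a larger set of families that is not reported. The patterns of Myh1, of Clec1b and Mmrn1 and of the split of calls were also found in these data, and their tests were written before the values they measure were seen, with exceptions given beside Myh1 and the split of calls. Of 30 CC and CXC chemokine genes, 14 were higher and 12 lower in lung by limma's test at an adjusted p under 0.05, with Cxcl3 counted as higher although its probes disagreed. Ccl6 (5.80 ± 0.11; SD, n = 2), Cxcl17 (4.46 ± 0.02), Ccl21 (4.35 ± 0.06), Ccl19 (3.24 ± 0.01) and Cxcl11 (3.08 ± 0.13) were higher. Ccl7 (-7.45 ± 0.06), Ccl2 (-6.92 ± 0.04), Ccl12 (-5.78 ± 0.06), Cxcl2 (-5.41 ± 0.04) and Cxcl6 (-2.97 ± 0.23) were lower. Of 17 chemokine receptors, 13 were higher and 1 lower, with Cxcr6 and Cxcr1 both at 4.14 on the log2 scale. These splits were 15 and 11, and 14 and 1, with array medians subtracted.

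All 15 cytosolic aminoacyl-tRNA synthetase genes were lower in lung (median -1.34; 13 lower with array medians subtracted), as were 9 of 12 tubulin genes, with 1 higher (median -1.39). Of 37 proteasome subunit genes, 22 were lower and 10 higher (16 and 11 with array medians subtracted), with a median of -0.27 against -0.22 for all genes. The highest were the immunoproteasome subunits Psmb9 (2.51), Psmb10 (2.06) and Psmb8. Among 19 claudins, 8 were higher and 8 lower (8 and 6 with array medians subtracted), led by the endothelial Cldn5 at 5.03 and the alveolar Cldn18 at 4.20. The sizes were one-sided: 8 claudins were at least 2-fold higher in both arrays and 1 at least 2-fold lower, Cldn9 at -1.80. Among 11 aquaporins, 4 were higher and 6 lower (5 and 5 with array medians subtracted), and 3 were at least 2-fold higher and 1 at least 2-fold lower in both arrays. Aqp5 (4.84), Aqp4 (4.27), Aqp3 (3.13) and Aqp9 (0.77) were higher. Aqp1, a water channel of lung endothelium, lay at -1.17, with Aqp11, Aqp6, Aqp8, Aqp2 and Aqp12a also lower. All 6 insulin-like growth factor binding protein genes were lower (4 with array medians subtracted), from -0.29 for Igfbp5 to -2.22 for Igfbp4.

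Clec1b and Mmrn1 were among the 4 highest genes, and both are expressed by platelets, which need not be their only source. Platelets and megakaryocytes in the lung sample are a candidate source: of 12 other platelet genes, none of them in the fixed lists, 10 were higher and 2 lower, 9 were at least 2-fold higher in both arrays, and their median was 1.49. Gp5 (3.37) and Treml1 (3.36) were far above 0, but the abundant platelet transcripts Pf4 (1.08) and Ppbp (1.32) were much nearer to it than Clec1b (8.38). Lymphatic endothelium stays open, with 7 of 12 genes higher, 4 lower and a median of 0.65 (2 of the genes are also in the fixed lists): Lyve1 and Ccl21 were high, and Prox1 was at -0.05. Expression of Clec1b by another lung cell was not tested.

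Myh1, a fast skeletal muscle myosin measured by 1 probe, was 266-fold lower in lung. Skeletal muscle cells in the mix1 cultures may account for it, but 21 other skeletal muscle genes had a median of -0.49 with an SD of 1.80 over genes, 6 higher and 13 lower, which decides neither way. Des, 1 of these genes, is also in the fixed smooth muscle list. The bound set beforehand to speak against muscle cells, a median above -0.5, was passed by less than the standard error, and the demand to pass it by that much was added after the value was seen. Myl1 (-1.57), Cacna1s (-1.37), Myh8 (-1.09), Atp2a1 (-0.97) and Tnnt3 (-0.53) were lower by much less than Myh1, while Mybpc2 (4.45 ± 0.90; SD, n = 2), Chrng (3.77 ± 0.48), Ckm (3.16 ± 1.34; 4.11 and 2.21 in the arrays) and Des (2.04 ± 0.13) were higher. Of the 21 genes, 14.3% were 2-fold lower in both arrays, Myh2 (-2.57) most, so a single deviant probe also remains open.

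More calls were lower than higher in lung (60.2%, which would be the higher share if the sign of the ratios were turned). With array medians subtracted, 49.7% of calls were lower, but subtracting medians balances the ratios around 0 by construction, a limit of this test recognised after its value was seen. Centring of the arrays therefore stays open as an explanation, and no biological explanation was tested.

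Of the 19595 probes without a gene name, 28.7% were at least 2-fold apart in both arrays, more of them higher than lower (3608 higher, 2024 lower, the opposite if the sign were turned), against 33.7% of named probes (3529 higher, 3344 lower). In 34 genes, probes disagreed by direction, most widely for Cxcl3, whose 2 probes lay at 8.20 and -3.67, so that its mean of 2.26 describes neither.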
